A study of Homo sapiens with 2 samples.

How the data were processed

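RNA levels were measured in PC3 cells, an established human prostate cancer cell line first derived from a bone metastasis. One sample was a culture grown in vitro. The other was a bone marrow metastasis: per the labels' protocols, cells labelled with the near-infrared fluorescent protein iRFP720 were injected into the heart of immunodeficient nude mice, and labelled cells were sorted from the marrow 5 to 7 weeks later. Total RNA was prepared on columns and labelled with Cy3 by a kit for low RNA input, per the labels' protocols. Each sample was hybridised to 1 array, and both arrays lay on the same slide, so the groups did not differ in slide. The number of mice behind the metastasis sample is not given in the sources used here.

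The deposited scanner files hold the intensity of each spot on a linear scale, with 62976 spots per array. Per the file headers, the intensity values were made with Agilent Feature Extraction 10.7.1.1 on a 1-colour array of design 072363, whose probe coordinates refer to hg19 (GRCh37). The submitters' processing notes list Agilent Feature Extraction 9.5.1.1, and which of these versions made the files was not settled. The processed intensity is the spot signal after background subtraction and detrending across the array, with dim spots replaced by a small positive value from the software's error model, per the file headers. A deposited value table holds 58201 probes on a linear intensity scale. Its columns both had a median of 5.31, and their sorted values differed by at most 0.341 intensity units, as quantile normalization gives. Within each array they ranked the probes as the processed signal did, with a rank correlation across probes of 0.99999 on both arrays. That table was used only as an alternative.

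Log2 of the processed signal minus the array's own 75th percentile over all 60901 non-control spots was taken as the level. The 75th percentile was 215.1 intensity units in the in vitro culture and 87.8 in the bone marrow metastasis. Control spots, numbering 2075 per array, and spots marked as non-uniform or population outliers, 74 and 64, were left out. No gene spot was saturated. Spots of 1 probe were averaged, which left 58195 probes. A gene took the probe with the highest mean level over both arrays. It counted as measured on both arrays if that probe was marked well above background on both. A gene well above background on 1 array only was given a lower bound of its fold, from the bright value over the higher of the dim probe's own value and the lowest signal of any probe well above background on the dim array.

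Gene names were updated through a table of RefSeq names (assembly GRCh38.p14, names only). Of the probes, 31100 were named by accession, 3366 by current symbol and 496 by an older symbol, and 23233 kept the name in the file. Probe coordinates are those of the files. Exon and UTR annotation was not used here.

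With 1 array per group no test across samples could be made, no p-value is given, and the number of arrays limits the precision. No difference reported here has a replicate check. The error that the files give is technical. The SD of log2 signal over the 10 replicate spots of a probe had a median of 0.06 on each array, over 263 probes measured on both arrays. The error that the scanner software attaches to a gene's log2 difference had a median of 0.21, with a 5th percentile of 0.20 and a 95th percentile of 0.32. Different probes of 1 gene agreed less well. Among 3665 genes with more than 1 probe measured on both arrays, the SD of the difference between probes had a median of 0.39, and in 63.3% of these genes all probes lay on the same side of 0.

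The 33 gene lists, the processing alternatives and the rule for named genes were fixed before the data were examined. A list with at least 5 members measured on both arrays was described by the median of their differences and by its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. It was said to stand apart below percentile 2.5 or above percentile 97.5, as a description of these arrays and not a test of the conditions. The named genes were the 12 with the largest difference in each direction among genes measured on both arrays with a RefSeq mRNA accession, a mean level at or above the lower quartile, and other measured probes of the same sign. The 6 largest lower bounds in each direction, and the 2 highest and 2 lowest members of each list, were also named. For lists of host cell markers, the members with the highest level on the marrow array were added. Some genes that the rule picked are not reported here. Further list members were given as examples after their values were seen.

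Alternatives were normexp background correction (offset 50) with the 75th percentile scaling, quantile normalization, centring each array on the median of the genes measured on both, loess of the difference on the mean level (span 0.3), the deposited values, no filter on dim probes, a filter at the median level, the mean over the probes of a gene, random lists without level matching, and 2 other definitions of a gene bright on 1 array only. A further scaling, to the 75th percentile over probes well above background on both arrays, was chosen after seeing the data, because 43.7% and 39.4% of the spots were well above background. Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp.

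The counting and list steps were tested on simulated data, in which the culture array was set against a simulated array of 24128 probes with a trend on signal level. Of 100 probes changed by 1.5 on the log2 scale, 91 passed the 2-fold line in the right direction, and of 100 changed by 2.5, 100 did. Of 23928 unchanged probes, 146 passed it. The simulated noise was drawn independently for each probe, from the replicate spots and a small normal term, with no variation between samples. It was smaller than the median SD of 0.39 between probes of 1 gene on the real arrays. These counts therefore check the steps and give no error rate for the real comparison. Of 60 unchanged lists of bright probes, 4 lay outside the percentiles with level matching and 58 without. Of 20 lists lowered by 0.5, 20 were found below. The simulated lists were random draws without shared variation between their genes, so these list counts give no error rate for the real lists either.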

Results

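Gene expression was compared between PC3 prostate cancer cells kept in culture and PC3 cells recovered from bone marrow metastases in mice, with 1 array for each. The comparison asks how the expression of the cells sorted from the marrow differed from that of the cells in the dish. Effects of taking the cells out of the marrow and sorting them cannot be told apart from effects of growth there. All differences are given as bone marrow metastasis minus in vitro culture, or as a fold, after each array was scaled to its own 75th percentile. On the culture array 26612 of the 60901 gene spots were well above background (43.7%), and on the marrow array 23989 were (39.4%). Of 43403 genes, 16054 were measured on both arrays, with a median log2 difference of -0.05. There were no replicates, so no difference below has a test. The scanner software's error of a log2 difference had a median of 0.21 and covers the measurement of the spots only.

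Among genes measured on both arrays, the largest differences in levels exceeded 10-fold. HAPLN1, which links hyaluronan to proteoglycans in the extracellular matrix, was 22.2-fold higher in the metastasis (log2 difference 4.47). EDIL3, a secreted ligand of integrins, was 17.1-fold higher. The secreted matrix protein OLFML2A was 26.4-fold higher by its brightest probe, but another probe gave a log2 difference of 0.99. The transcription factor DACH1 was 22.9-fold higher, and its other probe gave 3.96. EGR1 and FOS, transcription factors induced within minutes of a stimulus, were 12.3-fold and 10.71-fold higher. Whether the recovery and sorting of the cells raised them was not tested. The remaining genes named at this end were HBA2 (22.1-fold), an alpha-globin gene, PLAAT4 (12.8-fold), SMARCD3 (11.2-fold), a subunit of a chromatin remodelling complex, SEMA3A (11.2-fold), a secreted guidance protein, CIMAP1D (11.0-fold), and the lysosomal protease CTSO (10.8-fold).

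At the other end, SPANXB1 and SPANXC, members of a family normally expressed in the testis, were 42.1-fold and 20.6-fold lower in the metastasis. Probes for members of this family can share targets. BDKRB1, a bradykinin receptor, was 25.2-fold lower (log2 difference -4.65). CGB3, a subunit of chorionic gonadotropin, was 25.1-fold lower. The protease inhibitor TFPI2 was 19.3-fold lower. AOX1 (18.2-fold), an aldehyde oxidase, SBSN (15.1-fold), AFP (14.98-fold), the fetal serum protein alpha-fetoprotein, and LHFPL6 (13.3-fold) were also named at this end.

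**Figure D1:**
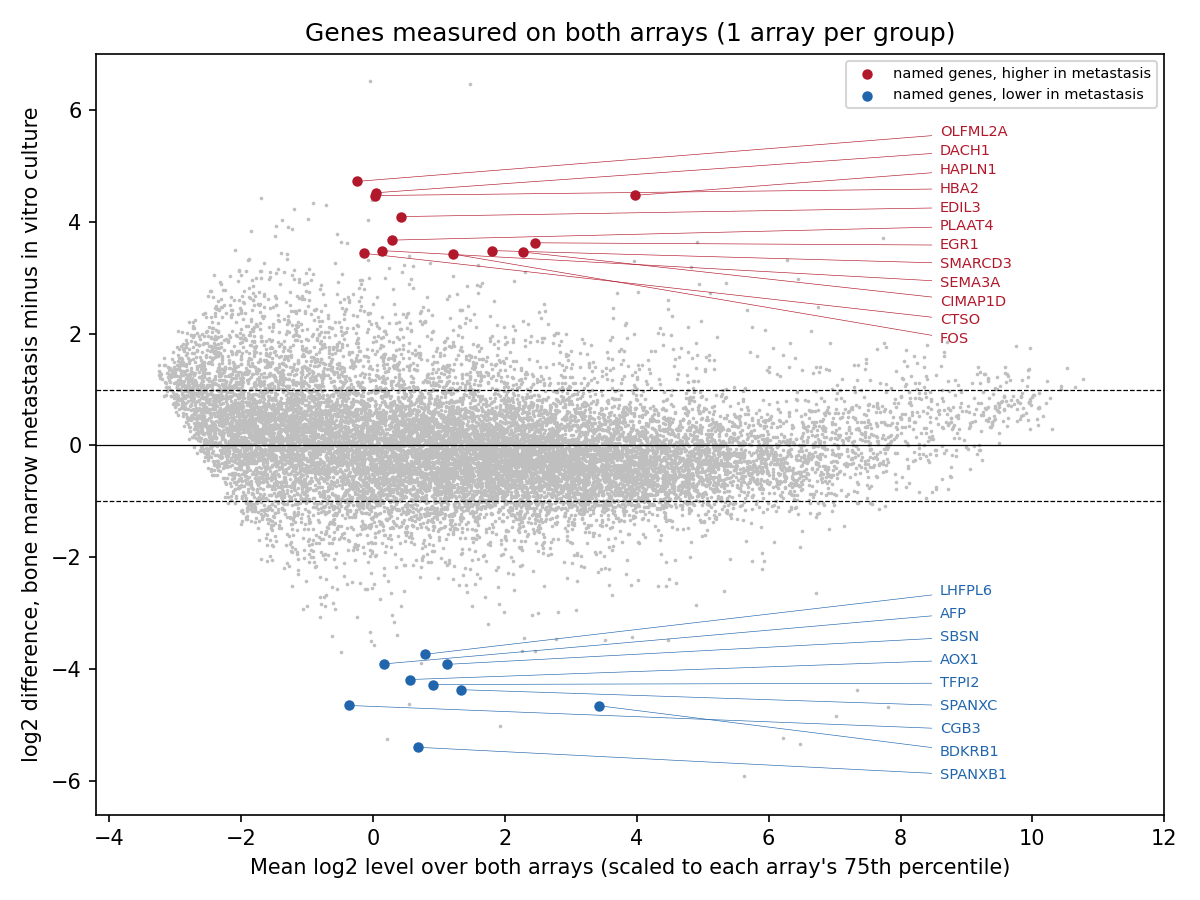
Each point is 1 of the 16054 genes measured on both arrays, except that SNAR-G1 (-6.68) lies below the range drawn. The horizontal axis is the mean log2 level and the vertical axis the log2 difference, bone marrow metastasis minus in vitro culture. Dashed lines mark 2-fold. Labelled genes are the named genes with the largest differences, from 4.72 for OLFML2A to -5.40 for SPANXB1, and the cloud lies above 0 among the dimmest genes.

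Of the genes measured on both arrays, 1948 were at least 2-fold higher in the metastasis and 1464 at least 2-fold lower. At 4-fold the counts were 412 and 169. The split depended on the scaling: 57.1% of the genes past the 2-fold line were higher in the metastasis, against 32.4% after normexp background correction, 68.6% after centring on the median and 82.1% when the 75th percentile was taken over probes well above background on both arrays. This last scaling, chosen after seeing the data, moved the median of all genes by 0.31, and centring on the median moved it by 0.12. The difference also varied with the level. In the lowest quartile of mean level the median difference was 0.41, with 1016 genes at least 2-fold higher and 227 lower. In the highest quartile the median was -0.22, with 216 higher and 316 lower. Among genes at or above the median level, 37.7% of those past the 2-fold line were higher. The filter itself favours higher calls among dim genes. After scaling, the lowest signal well above background was -2.758 on the marrow array and -4.015 on the culture array. A gene dim in the culture could therefore count as 2-fold higher but not as 2-fold lower. How much of the excess of higher genes this gives was not tested. Among genes named below, PDGFRB, MX1, ITGA10, FOSB, LAMA4 and JUP had culture levels from -3.84 to -3.01. These lay below -2.758, so as genes measured on both arrays they could only be higher in the metastasis.

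A further 665 genes were well above background on the marrow array only and 2507 on the culture array only. What made these counts unequal was not tested. The calls were made before scaling, where the lowest signal well above background was 13.3 in the culture and 13.0 in the metastasis. The marrow array was dimmer, with a 75th percentile of 87.8 against 215.1. After scaling, that lowest signal was 1.26 higher on the log2 scale on the marrow array. Where the dim probe lies below the lowest signal, this offset alone gives a gene of the marrow array a bound past 2-fold. All 665 genes of the marrow array had a bound of at least 2-fold, whereas of the 2507 genes of the culture array 258 had such a bound and 1658 had no bound and need not be lower in the metastasis. MMP1, the interstitial collagenase, was at least 309-fold lower in the metastasis. It was followed by TENM2, a transmembrane adhesion protein (at least 114-fold lower), SLC7A11, the cystine transporter (at least 28.5-fold), the DNA repair gene MGMT (at least 26.6-fold), PRICKLE1 (at least 24.0-fold) and IGFBP3, which binds insulin-like growth factors (at least 23.4-fold). In the other direction GJB2, a gap junction protein, was at least 118-fold higher in the metastasis. MS4A6A, a membrane protein known from monocytes and macrophages, was at least 26.7-fold higher, with a second probe not well above background on either array. SYT12 (at least 19.4-fold), ENTPD8 (at least 16.8-fold), SPINK2 (at least 16.6-fold) and CLRN2 (at least 13.5-fold) followed. With a weaker definition of signal, a spot positive and significant against background, the counts became 2757 and 4566.

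In hg19 (GRCh37) the probe for HAPLN1 lay on chromosome 5 from 82937323 to 82937382, that for EGR1 on chromosome 5 from 137804891 to 137804950, that for GJB2 on chromosome 13 from 20761915 to 20761974, and that for MMP1 on chromosome 11 from 102660697 to 102660756. The probe for BDKRB1 lay on chromosome 14 from 96731011 to 96731070.

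Of the 33 gene lists, 25 had enough members measured on both arrays, and of these 8 stood apart below and 3 above the matched random lists. By chance about 1.25 lists would lie outside. Members well above background on 1 array only enter neither these medians nor the splits into higher and lower below, unless their bounds are named.

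Genes of cell division were lower in the metastasis. All 20 genes of the G2/M list were measured; 19 were lower, 13 of them at least 2-fold, and the median was -1.14 (percentile 0). AURKB and PLK1, kinases of mitosis, were 5.64-fold and 4.12-fold lower, TOP2A was 3.32-fold lower and TPX2 was 3.29-fold lower. CENPF differed by -0.16 and its other probe by 0.67, with the sign turned under quantile normalization, loess, the deposited values and the scaling to probes bright on both arrays. The proliferation marker MKI67 differed by 0.19, but its 3 probes ran from -1.13 to 1.19 and its sign turned under normexp. All 20 genes of DNA replication were lower, 4 of them at least 2-fold, with a median of -0.52 (percentile 2.44). This list no longer stood apart under 6 of the alternatives, among them quantile normalization (percentile 3.55) and normexp (percentile 3.99). RRM2, a subunit of ribonucleotide reductase, was 7.10-fold lower by its brightest probe while another probe gave 1.41, and GINS2 was 2.31-fold lower. PCNA and RFC3 differed by -0.02 and -0.18, with signs that turned under other scalings.

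All 16 measured genes of glycolysis were lower, 5 of them at least 2-fold, with a median of -0.80 (percentile 0). ENO2, an enolase, was 4.40-fold lower and the pyruvate kinase PKM 2.31-fold lower. ALDOA and GAPDH differed by -0.22 and -0.06, and both turned positive with the scaling to probes bright on both arrays. Of 24 genes of oxidative phosphorylation 20 were lower, 2 of them at least 2-fold, with a median of -0.35 (percentile 1.48), but the list no longer stood apart under 6 of the alternatives, among them quantile normalization (percentile 3.16) and loess (percentile 2.77), and its median was -0.04 with the scaling to probes bright on both arrays. CYC1 and SDHB were 2.35-fold and 2.25-fold lower, while UQCRB and COX7C were 1.39-fold and 1.38-fold higher; the other measured probe of UQCRB gave -0.30. The hypoxia response did not stand apart (17 genes, median -0.26, percentile 34.9), except among the brighter genes, where it lay below (median -0.86, percentile 0.12). ADM and CA12 were 4.91-fold and 4.09-fold lower, and VEGFA and INSIG2 were 1.59-fold and 1.57-fold higher, with another VEGFA probe at -0.96. Cholesterol synthesis did not stand apart either (21 genes, median -0.29, percentile 31.5). MSMO1 was 3.72-fold lower and FDFT1 1.87-fold lower, against differences of 0.41 for SC5D and 0.13 for INSIG1, the last of which turned negative under normexp.

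The lists of NF-kB inflammatory genes, of the unfolded protein and amino acid response and of heat shock proteins stood apart below. All 12 measured NF-kB genes were lower, 8 of them at least 2-fold, with a median of -1.47 (percentile 0), and 3 more were well above background on the culture array only. Of these CXCL6 was at least 5.28-fold lower and CXCL8 at least 1.36-fold lower, and CSF2 had no bound. The chemokine CXCL3 was 5.57-fold lower, TNFAIP2 4.70-fold lower and CXCL1 4.29-fold lower, while RELB and CCL2 were 1.39-fold and 1.43-fold lower. Of 19 genes of the unfolded protein and amino acid response 15 were lower, 10 of them at least 2-fold, with a median of -1.08 (percentile 0). The lower members included the enzymes of serine and asparagine synthesis, PHGDH (11.2-fold), PSAT1 (5.52-fold) and ASNS (4.18-fold). DDIT4 was 3.86-fold higher and the chaperone HSPA5 1.74-fold higher. Of 12 heat shock genes 10 were lower, 2 of them at least 2-fold, with a median of -0.76 (percentile 0.06). BAG3 and HSPA8 were 2.29-fold and 2.17-fold lower. HSPB1 differed by 0.51, with another probe at -0.54, and HSPA1A by 0.24, which turned negative under normexp.

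Of 17 TGF-beta targets 11 were lower, 9 of them at least 2-fold, and 6 were higher, 2 of them at least 2-fold, with a median of -1.11 (percentile 0; 6.61 under normexp). The lower members included ID3 (7.23-fold), IL11 (4.54-fold) and TGFBI (4.12-fold). SKI, which represses this pathway, was 3.80-fold higher and PMEPA1 2.92-fold higher. The mesenchymal list did not stand apart (13 genes, median -0.52, percentile 4.005), though it did under quantile normalization (percentile 0.1) and loess (percentile 0.25). Its lower members included TGM2 (5.98-fold lower), and its highest were S100A4 (1.88-fold higher) and CDH2 with a difference of 0.28, which turned negative under normexp. The epithelial list did not stand apart (7 genes, median 0.04, percentile 48.8). JUP, the junction protein plakoglobin, was 16.6-fold higher and MUC1 2.48-fold higher, whereas KRT18 was 2.71-fold lower and CLDN4 differed by -0.24, with a sign that turned under normexp and the scaling to probes bright on both arrays.

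Collagens and laminins moved in both directions. Among the 13 measured on both arrays 8 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 1.40 (percentile 100). LAMA4 was 8.51-fold higher, COL4A5 4.69-fold, COL6A1 4.50-fold and LAMA5 2.91-fold. COL4A2 was 11.0-fold lower and LAMA1 2.16-fold lower. Another 7 members were well above background on the culture array only, among them COL13A1 (at least 15.3-fold lower) and COL4A1 (at least 7.83-fold lower). With these at their bounds the median of the 20 members was -0.15. Matrix proteases and their inhibitors did not stand apart (14 genes, median 0.28, percentile 93.5), except under normexp (percentile 99.4) and among the brighter genes (percentile 99.0). MMP14, a membrane-bound collagenase, was 3.53-fold higher and ADAMTS1 2.75-fold higher, while PLAUR, the urokinase receptor, was 2.73-fold lower. The integrins did not stand apart (9 genes, median 0.22, percentile 85.7). ITGA10 was 4.57-fold and ITGA7 1.92-fold higher, ITGA5 was 2.02-fold lower, and ITGA3 differed by -0.23, which turned positive under 4 other scalings.

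Genes linked to bone metastasis and bone matrix did not stand apart (12 genes, 6 higher and 6 lower, percentile 56.0). Another 4 members were well above background on the culture array only, among them MMP1. With these at their bounds, 6 of the 16 members were higher and 10 were lower or at 0. NOG, a secreted BMP antagonist, was 5.12-fold higher and RUNX2, the transcription factor of osteoblasts, 3.35-fold higher. IL11 was lower, and DKK1, a secreted Wnt inhibitor, was 2.38-fold lower. Of androgen receptor targets 8 were measured (median -0.42, percentile 12.4). NDRG1 was 3.53-fold lower, PMEPA1 was higher, and HOXB13 differed by 0.27 with a sign that turned under quantile normalization, loess and the deposited values. Of the neuroendocrine genes only ENO2 and CHGB (2.87-fold higher) were measured on both arrays.

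**Figure D2:**
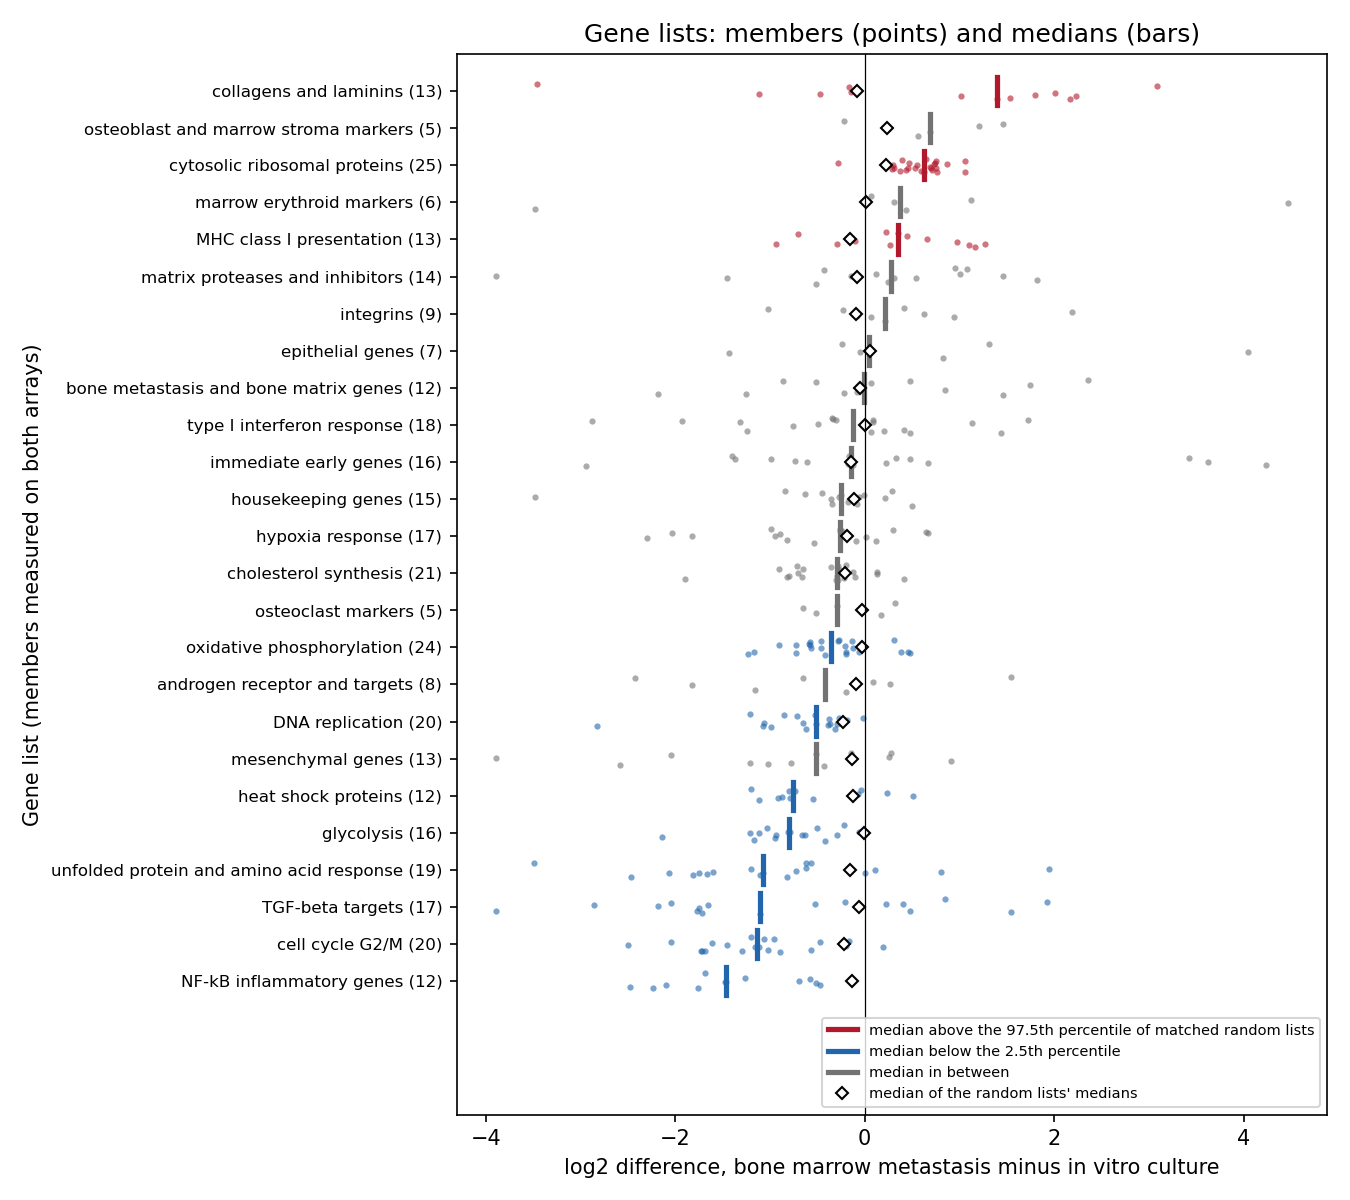
Points are the members of each of the 25 gene lists measured on both arrays, bars are list medians and diamonds are the medians of 10000 level-matched random lists; the horizontal axis is the log2 difference, bone marrow metastasis minus in vitro culture. Medians run from -1.47 for NF-kB genes to 1.40 for collagens and laminins, and the ribosomal protein median of 0.63 became -0.06 under quantile normalization.

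Of 25 cytosolic ribosomal protein genes 24 were higher in the metastasis (median 0.63, percentile 99.4), RPLP1 and RPS2 by 2.09-fold each, with the lowest of the 3 RPS2 probes at 0.11. The list median, however, was -0.06 under quantile normalization and with the deposited values. RPLP0 differed by 0.29 and RPS3 by -0.28, and both signs turned under other scalings. MHC class I presentation stood apart above (13 genes, 9 higher, median 0.35, percentile 98.1), except against random lists not matched on level (percentile 92.4). Its median was 0.02 under normexp and 0.66 with the scaling to probes bright on both arrays. PSMB10 and HLA-E were 2.41-fold and 2.24-fold higher. B2M, the light chain of these molecules, was 1.62-fold lower, and NLRC5 differed by -0.93, which became 0.02 under normexp. The type I interferon response did not stand apart (18 genes, 9 higher and 9 lower, percentile 28.3). IFI27 and IFI6 were 7.35-fold and 3.82-fold lower, and MX1 and IRF7 3.30-fold and 2.70-fold higher. Immediate early genes did not stand apart as a list (16 genes, 7 higher and 9 lower, percentile 50.4). FOSB was 18.8-fold higher beside EGR1 and FOS, whereas FOSL1 was 7.70-fold lower and ATF3 2.65-fold lower by the brightest of its 3 probes, the highest of which gave 0.27. The housekeeping genes did not stand apart (15 genes, median -0.25, percentile 22.9). TFRC, the transferrin receptor, was 11.2-fold lower, TBP was 1.79-fold lower, and ACTB differed by 0.50, which turned negative under quantile normalization, loess and the deposited values.

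Markers of the host marrow were examined because the sorted cells came from mouse bone. The probes were designed for human transcripts, and how they bind mouse RNA was not measured. Of the 122 marker genes on the array, 82 had no probe well above background in the culture, and 2 of these, AIF1 and PTPRC, had a probe well above background in the metastasis. The neutrophil genes S100A8 and S100A9 and the globin gene HBB were not well above background on either array. Both overlapping probes of HBA2, on chromosome 16 from 223555 to 223619, were higher (4.47 and 4.89), while another probe, from 222889 to 222948, was not well above background on either array. AIF1, a macrophage protein, was at least 7.84-fold higher by 1 of its 2 probes, and PTPRC, the common leukocyte antigen, at least 3.44-fold by 1 of its 5 probes.

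The erythroid markers (6 genes, median 0.37, percentile 83.2), the osteoblast and stroma markers (5 genes, median 0.69, percentile 85.1) and the osteoclast markers (5 genes, median -0.30, percentile 24.7) did not stand apart. Another 3 osteoblast and stroma markers were well above background on the culture array only. With these at their bounds, 4 of 8 were higher and 4 lower or at 0, with a median of 0.28. EPB42 was 2.18-fold higher, and KLF1 differed by 0.07 with a sign that turned under other scalings. SPARC, a secreted matrix protein, was 2.75-fold higher, PDGFRB 2.30-fold higher and LEPR 1.61-fold higher, and SP7 and BGLAP differed by 0.56 and -0.21, the latter turning positive under normexp. PDGFRB lay near the lowest signal well above background on both arrays, at -3.84 in the culture and -2.64 in the metastasis. Its difference of 1.20 (scanner error 0.44) was smaller than the offset of 1.26 between those lowest signals after scaling. TNFRSF11A and MMP9 were 1.57-fold and 1.42-fold lower. NFATC1 differed by 0.32, CTSK by 0.18 and OSCAR by -0.30, the last 2 with signs that turned under other scalings. Another probe of OSCAR gave 1.59, and with the mean over probes the osteoclast median was 0.18. Of the lists with too few measured members, the B lineage had CD79A (3.22-fold higher), the megakaryocytes GP1BB (3.40-fold higher) and GP9 (-0.31), and the adipocytes CIDEC (2.51-fold lower). The neutrophil list had MMP9 and CSF3R (0.14). The monocyte and macrophage list had CD14 (0.64), ADGRE1 (0.62), FCER1G (-0.26) and TYROBP (-0.15). The pan-leukocyte list had CORO1A (0.29), SRGN (-0.01), RAC2 (-0.12) and ITGB2 (-0.14), and the endothelial list CDH5 (0.30). For GP9, CSF3R, CD14, FCER1G, TYROBP, CORO1A, SRGN, RAC2, ITGB2 and CDH5 the sign turned under at least 1 other scaling.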

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

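The spike-in comparison and the tests in this part were chosen after the values were seen, except the test of probe GC content and the test on brighter probe pairs.

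Control RNA added to the samples was not part of the comparisons and gave a different signal on each array. The 7 spike-in probes well above background on both arrays were brighter on the marrow array before scaling, with a median log2 difference of 0.63 and a range of 0.43 to 0.74. The SD over the spots of a spike-in probe had a median of 0.08 in the culture and 0.07 in the metastasis. The genes measured on both arrays had a median unscaled difference of -1.34, which is -1.97 relative to the spike-ins. The amount of control RNA per amount of sample RNA is not given in the sources used here, so the levels were not scaled to it. The directions given in the report depend on this choice: relative to the spike-ins every difference is 1.92 lower on the log2 scale, 471 of the 7664 genes with a difference above 0 stay above it, and none of the 8 list medians above 0 does.

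Genes of chromosome 15 were lower in the metastasis as a set. This chromosome had the lowest median of the autosomes after loess on the level (-0.28). The medians of the others ran from -0.12 for chromosome 12 to 0.16 for chromosome 13. The random gene sets used below mix genes of all autosomes, so they do not show how far whole chromosomes differ. The median of the 516 genes measured on both arrays lay 0.23 below that of the 14904 other autosomal genes (-0.23). The gap was -0.27 after loess on the level. The chromosome was singled out by its value after that loess, so this gap is no separate test of a trend with signal level. The GC content of the probes is argued against, since the gap was -0.26 after a further loess on GC. The lowest of 1000 random gene sets reached -0.11 after loess on the level and -0.12 after that on GC. The gap shrank to -0.07 under normexp, and was -0.28 there among genes at or above the median level. Whether the copy number of chromosome 15 was lower than in the cultured cells stays open. Of windows of 20 neighbouring genes, 92% had a median below the other autosomal genes, but with the genes in random order the share was 92% as well (median of 1000 orders), so it restates the lower median. DNA was not measured, and an effect of the marrow on these genes was not tested.

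Probes towards the 5' end of a transcript were higher in the metastasis relative to 3' probes of the same transcript. Over 714 transcripts with probes more than 2000 nt apart, the 3' minus 5' difference had a median of -0.40, against 0.06 for 552 transcripts with probes within 500 nt. A trend with signal level as the whole cause is argued against by the value after loess on the level, -0.36 (95% bootstrap interval over transcripts -0.45 to -0.25). A share of it stays open, since the 117 pairs with both probes above the median level gave a smaller difference, -0.20 as scaled (-0.43 to -0.05) and -0.18 after loess (-0.39 to -0.002). The condition set beforehand, a median below -0.1 with an interval that leaves out 0, was met, but the interval reaches above -0.1. Degradation of the metastasis RNA would lower the 5' probes, the reverse of this pattern, so these values are no separate test of it. Lower integrity of the culture RNA and other choices of 3' ends between the conditions were not tested.

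HBA2 and single probes of AIF1, PTPRC and MS4A6A were higher in the metastasis, which RNA from mouse marrow cells could give. Of the 82 host marker genes dim in the culture, 2.44% were well above background in the metastasis, against 2.999% of 5901 other genes with a RefSeq mRNA accession. The listed markers thus showed no excess. MS4A6A, a gene known from monocytes and macrophages that was not on the lists, was at least 26.7-fold higher. S100A8, S100A9 and HBB, abundant in marrow, were not well above background. The metastasis cells were sorted for their label, which removes host cells as far as the sort is pure. The explanation stays open for HBA2, AIF1, PTPRC and MS4A6A, because human probes need not bind mouse transcripts and expression by the tumour cells themselves was not tested.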

How the results depend on the processing

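The data hold 1 array per group, so no setting left out a replicate. No paired analysis was possible because the labels give no pairing and no result comes from a test.

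The counts at 2-fold moved little under quantile normalization (1664 higher and 1275 lower), loess (1604 and 1254) and the deposited values (1706 and 1320). Normexp gave 891 higher and 1861 lower at 2-fold, of which 891 and 1053 were also so in the main setting, and 70 higher at 4-fold. Without a filter the counts were 21813 higher and 2555 lower at 2-fold and 2468 and 530 at 4-fold, since unmeasured probes sit at a floor that the scaling then shifts by group. Restriction to the brighter 8027 genes left 473 higher and 781 lower at 2-fold and 70 and 80 at 4-fold. Fewer genes were counted, and the split turned: 37.7% of the genes past the 2-fold line were higher, against 57.1% in the main setting. The excess of higher genes in the main setting thus lay among the dimmer genes. Scaling to probes bright on both arrays, chosen after seeing the data, gave 3026 and 660 at 2-fold and 675 and 100 at 4-fold, because it adds 0.31 to every difference. With positive and significant spots as the definition, 7323 genes were bright on 1 array only, 2757 on the marrow and 4566 on the culture array.

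Of the 25 list medians, 16 kept their call under every alternative run: those of G2/M, glycolysis and NF-kB among them. Centring on the median and the scaling to probes bright on both arrays add the same amount to every gene. These alternatives could therefore not change a percentile. The deposited values nearly repeat the quantile normalization, with a correlation of the log2 differences of 0.99986. DNA replication no longer stood apart under normexp (-0.80), quantile (-0.30), loess (-0.29), the deposited values (-0.29), brighter genes (-0.52) and the mean over probes (-0.52). Oxidative phosphorylation no longer did under quantile (-0.26), loess (-0.27), the deposited values (-0.25), no filter, brighter genes and unmatched lists (-0.35 each). TGF-beta targets no longer did under normexp (-0.44), MHC class I against unmatched lists (0.35), and ribosomal proteins under loess (0.072) and among brighter genes (0.63). Ribosomal proteins turned negative under quantile (-0.065) and the deposited values (-0.062), and collagens and laminins without a filter (-0.17), where members dim in the metastasis enter. Mesenchymal genes stood apart below under quantile (-0.74), loess (-0.63), the deposited values (-0.70) and no filter (-0.47), hypoxia genes below among brighter genes (-0.86), and matrix proteases above under normexp (0.30) and among brighter genes (0.55). Where no cause is named, the cause was not tested.

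Of 133 named genes measured on both arrays, 106 stayed on the same side of 2-fold under every alternative that gave a value, and none of those past 2-fold turned its sign. Scaling to the spike-ins was not among these alternatives. Relative to the spike-ins every difference is 1.92 lower, so named genes higher by less than that, such as SPARC (1.46), turn their sign there.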

Other observations

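The gene groups in this part were chosen after their values were seen. Among genes measured on both arrays, noncoding transcripts held the largest differences, 6.52 for a transcript named lnc-NAA35-1 and -6.68 for SNAR-G1. 7 of the 8 measured SNAR genes, small noncoding RNAs of a primate-specific family whose near-identical copies can share probes, were lower in the metastasis, from 20.7-fold for SNAR-B2 to 103-fold for SNAR-G1, while SNAR-C4 differed by 0.57. MALAT1, an abundant nuclear noncoding RNA, was 12.5-fold higher by the brightest of its 4 probes, but another probe gave 0.62. The 881 long noncoding RNA genes measured on both arrays had a median of 0.35, with 186 at least 2-fold higher and 39 lower, at percentile 100 among 1000 random lists matched on level. Their median was 0.23 to 0.66 under the 6 other scalings, background correction included. The 358 measured zinc finger genes with ZNF names had a median of 0.19, with 69 at least 2-fold higher and 9 lower (percentile 100). The 11435 protein-coding genes had a median of -0.19, which was 0.12 with the scaling to probes bright on both arrays.

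Aminoacyl-tRNA synthetases, which load amino acids onto tRNAs and include known targets of the amino acid response, were lower as a group. Of 17 measured genes with names ending in ARS1, 7 were at least 2-fold lower and none was at least 2-fold higher, with a median of -0.74 (percentile 0.1) and of -0.43 to -1.09 under the 6 other scalings. YARS1 was 3.82-fold lower, MARS1 3.01-fold, AARS1 2.99-fold and CARS1 2.76-fold, while QARS1 differed by 0.49. The 64 histone genes had a median of 0.28 (percentile 100), which became -0.03 under normexp. IGF2, a growth factor of fetal tissues, was 9.91-fold higher, with its probes at 3.18 and 3.31. CTSF, a lysosomal protease like CTSO, was 9.42-fold higher, while the 9 measured cathepsin genes together had a median of 0.01, which turned negative under 4 other scalings.

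Several list members named in the report lie on chromosome 15. PKM (-1.21), CA12 (-2.03) and B2M (-0.70) were lower in the metastasis, and RPLP1 (1.07) and EPB42 (1.12) were higher. Without the genes of this chromosome the G2/M median was -1.12, that of glycolysis -0.78, that of MHC class I presentation 0.40 and that of the TGF-beta targets -0.82.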
